A study of Homo sapiens with 6 samples.

How the data were processed

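RNA of F36P cells was measured in 6 libraries, 3 of cells with an ERG-expressing retrovirus and 3 with the empty retrovirus. Per the labels' protocols, polyadenylated RNA was captured on oligo-dT beads, fragmented and primed with random hexamers. Whether the libraries kept strand is not given in the sources used here, nor are the aligner, the counting tool and the gene annotation. Per the submitters' processing notes, the genome build was hg38 and edgeR 3.32.1 was used.

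The deposited table holds read counts per gene and library, in whole numbers, although its name speaks of CPM. The column totals range from 10257141 to 14803031 and so are not CPM, which sum to the same total in every library. The second-highest CPM of every one of the 14821 genes was at least 1.01, so the table had been filtered before deposit to genes above about 1 CPM in 2 libraries. Replicate numbers in the column headings match those in the sample titles. The headings of the control columns do not repeat the word used in the titles, and they were assigned to the vector samples because these are the only group besides ERG. No column of per-sample values was left unused (0 columns).

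The planned test, limma on log2(CPM + 1), had been fixed for CPM values before the data were examined. Since the table holds counts, edgeR 4.0.16 (in R 4.3.3) was used instead, with TMM normalisation and its quasi-likelihood test, two-sided. Genes with at least 1 CPM in at least 3 of the 6 libraries were tested, which kept 14203 genes and left out 618. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of its F statistic. CPM values are normalised by TMM and given as mean ± SD (n = 3 per group).

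The 26 gene lists were fixed before the data were examined: haemoglobin, haem and iron, red cell membrane, erythroid regulators, ETS family, stem and progenitor, megakaryocyte, myeloid (granulocyte and monocyte), mast cell with basophil and eosinophil, lymphoid, endothelial, stromal and epithelial, histone deacetylases, MEF2 with sirtuins and corepressors, proliferation, cyclins and cell cycle inhibitors, p53 targets, interferon, integrated stress response, cytokine receptors and JAK-STAT, immediate early and MAPK, cholesterol, glycolysis, adhesion and integrins, mitochondrially encoded genes, and replication histones. Some genes are in 2 lists. The 25 lists with at least 5 tested members were tested with limma 3.58.1 camera, which compares a list's genes with all others, at its preset correlation of 0.01. The test was repeated with the correlation estimated per list, where 0 of 25 lists passed (lowest adjusted p = 0.127). With fry, which tests whether a list's genes move on balance one way, 8 lists had an adjusted p under the threshold. They were the haemoglobin, haem and iron, red cell membrane, erythroid regulator, ETS family, stem and progenitor, megakaryocyte and mast cell lists.

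The genes named were chosen by a rule fixed before the data were examined. ERG and HDAC7 are always given. Then come the 12 largest rises and 12 largest falls among genes past the threshold, with all ERG libraries on one side of all vector libraries and a mean of at least 5 CPM in the higher group, leaving out unnamed loci, pseudogenes, antisense and readthrough transcripts. From each list up to 4 members past the threshold with the largest changes are named, or the 2 with the highest mean CPM where none passed. Names ending in P and a digit were left out only where GENCODE release 29 does not call the gene protein-coding, a reading of the rule that kept LTBP1. Some genes that the rule takes are not reported here, though they count in the totals of calls and lists. Other genes are said to have been chosen after their values were seen. Coordinates come from GENCODE release 29 on hg38, matched by gene name, which found 12772 of the 14203 tested genes.

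The counts of genes with near-identical copies are uncertain. For example, the pseudogene EEF1A1P5 had 452135 counts summed over the libraries against 177887 of its parent EEF1A1, and RPL13AP5 190023 against 22018 of RPL13A. The same holds for the alpha and gamma globin pairs and for the tryptase genes TPSAB1, TPSB2 and TPSD1. The totals limit the precision of genes with few counts. For 2 genes with 1 to 3 counts in a group the ratio is given with an exact binomial 95% interval, which covers counting error only.

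All pairs of libraries were compared by a chi-square test of their counts over genes with at least 20 counts. ERG replicates 1 and 2 differed by 2.20 per degree of freedom over 14575 genes, beyond the sampling noise of independent reads. All other pairs differed by 21.6 to 86.9. ERG replicates 1 and 2 were counted as 2 replicates. The library sets were defined from the correlations of log2 CPM after the data were seen and are not groups of the study. They entered as a term in added models, and log2 differences, an interaction term and splits of the libraries were also computed within or between them. P-values with the set term may be too low, since the sets were chosen on these data and ERG replicates 1 and 2 lie so close together. Log2 differences within a set were taken from log2 CPM with a prior count of 2, which shrinks changes of genes with few counts. They are therefore not the same measure as the fitted changes.

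The edgeR test was checked on simulated counts of the 14203 genes with the spread of the main comparison. It recovered 29 of 100 genes changed 2-fold and 84 of 100 changed 4-fold, and called 11 of 14003 unchanged genes. With a library-set term and the spread left by it, it recovered 78 and 94 of 100. The libraries were drawn independently in both runs, without a pair as close as ERG replicates 1 and 2, and in the first run without library sets. The number of unchanged genes called is therefore no check of the error rate in the real libraries. In simulated data 1 list of 20 genes raised 2-fold was called and 0 of 24 unchanged lists were. Each gene was drawn independently there, without library sets. The list simulation therefore does not check the preset correlation against genes that vary together.

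The alternatives fixed before the data were examined were limma with pseudocounts of 1, 0.1, 0.5 and 5, quantile normalisation, no intensity trend and robust fitting, edgeR with no filter, with a filter of 5 CPM, with median-ratio size factors and with the replicate number as a block, and leaving out each library. Those added afterwards were a library-set term, ERG replicates 1 and 2 summed, both together, scaling by library size only, robust edgeR and DESeq2 1.42.0. A separate edgeR fit on reads recovered from CPM was not needed, as the table holds counts.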

Results

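Messenger RNA of F36P, an established human acute erythroid leukaemia cell line, was sequenced in 6 libraries. In 3 of them the cells carried a retrovirus expressing ERG, a transcription factor of the ETS family, and in the other 3 the empty retrovirus (vector). All cells had been selected with 1 µg/ml puromycin for 4 days. The control columns were assigned to the vector samples as the only group besides ERG. The deposited table held whole-number read counts of 14821 genes. The totals were 12421407, 14169691 and 14803031 counts in ERG replicates 1, 2 and 3 and 11546541, 13615797 and 10257141 in vector replicates 1, 2 and 3. The labels call the replicates biological without saying from which cultures or transductions they came, so p-values measure the spread between these samples. The question stated by the submitters was how ERG inhibits erythroid differentiation, and what is compared here is RNA levels with ERG against vector.

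ERG itself stood at 97.4, 103 and 104 CPM (counts scaled to library size after TMM normalisation) in the 3 ERG libraries and at 28.1, 14.6 and 22.4 CPM in the 3 vector libraries. The gene lies on chromosome 21 from 38380027 to 38661780 (hg38, GENCODE release 29). Its level was 4.68-fold higher with the ERG virus, 101 ± 3.46 against 21.7 ± 6.76 CPM (SD, n = 3 each; log2 fold change 2.23, SE 0.23, edgeR adjusted p = 0.011). Without ERG replicate 1, ERG replicate 2 or vector replicate 3 the log2 fold change was 2.25, 2.22 or 2.25 and did not pass (edgeR adjusted p = 0.0716, 0.0729 and 0.0544). Reads of the introduced and of the cell's own ERG cannot be separated in a table of counts per gene. HDAC7, the histone deacetylase named in the series title (chromosome 12, 47782722 to 47833132), was at 428 ± 47.7 CPM in ERG and 501 ± 53.3 CPM in vector libraries. Its log2 difference of -0.23 did not pass the test (95% interval -0.59 to 0.14, edgeR adjusted p = 0.52). None of the 10 tested members of the histone deacetylase list passed, also when adjusted over the list alone (camera adjusted p = 0.698). With a term for the 2 sets into which the libraries fell, HDAC5, named after its value was seen, was higher (edgeR adjusted p = 0.00121), as it was with the replicate number as a block (0.0203) and without vector replicate 1 (0.0344). The 2 members with the highest level were HDAC7 and HDAC2, the latter at 274 ± 38.6 against 289 ± 38.6 CPM.

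With ERG, 11 of the 73 tested members of 4 erythroid lists passed as lower than with vector and 0 as higher, while 20 of the 41 tested members of the megakaryocyte, mast cell and stem cell lists passed as higher and 0 as lower. Not all members had that sign, as 13 of the 73 had positive and 6 of the 41 negative log2 differences. Each of these lists passed the camera test at its preset correlation, but with an estimated correlation 0 of 25 lists passed (lowest adjusted p = 0.127). In fry, which does not compare a list with other genes, their adjusted p lay between 0.0273 and 0.0315. The fetal globin genes HBG2 and HBG1 fell 4.50-fold and 3.99-fold, and the erythropoietin receptor EPOR fell 2.47-fold. The platelet integrin ITGB3 rose 14.6-fold, the mast cell receptor chain MS4A2 32.4-fold and the stem and progenitor cell marker CD34 3.54-fold. In all, 313 of 14203 tested genes passed an edgeR adjusted p of 0.05, 209 higher and 104 lower with ERG. Of these, 246 differed by at least 2-fold. Of all tested genes, 21.9% had the 3 ERG libraries all above or all below the 3 vector libraries. With 6 independent libraries this would be 10% by chance. ERG replicates 1 and 2 were far closer to each other than other pairs, so that figure may be too low here. With 5 libraries in place of 6, edgeR called 0 genes when ERG replicate 1 or ERG replicate 2 was left out (1278 and 1256 genes at an unadjusted p under 0.05), 19 without vector replicate 2 and 51 without vector replicate 3. It called 441 without ERG replicate 3 and 441 without vector replicate 1, and none of the 313, which were selected on the same libraries, changed sign. DESeq2 called 1006 genes with all libraries and 410 and 411 without ERG replicate 1 or 2, among them 300 and 297 of the 313, while limma called 0 in both cases.

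The libraries also differed in a way that cut across both groups. Across the tested genes, vector replicate 1 correlated more closely with ERG replicates 1 and 2 (r = 0.967 and 0.966) than with vector replicates 2 and 3 (r = 0.957 and 0.954). ERG replicate 3 correlated more closely with vector replicates 2 and 3 (r = 0.965 and 0.974) than with ERG replicates 1 and 2 (r = 0.962 with each). ERG replicates 1, 2 and vector replicate 1 are therefore called library set A and the other 3 libraries library set B, a division chosen after the data were seen. These are correlations across genes, which are not independent replicates. With the set as a term in the model, 1869 genes passed, 1022 higher and 847 lower, and all 313 genes were among them with the same sign. The sets were chosen on these libraries, and ERG replicates 1 and 2 lie far closer together than other pairs. The spread left by the set term may therefore be too small, and all p-values given with that term too low. With ERG replicates 1 and 2 summed, 1001 genes passed with the set term. The median size of the 313 changes was 1.56 on the log2 scale in the edgeR fit. It was 1.49 within set A and 1.40 within set B, in differences of log2 CPM. These used a prior count of 2, which shrinks changes of genes with few counts, so the values are not quite alike in measure. The 313 genes were selected on these same libraries, so a shared sign and a like size in both sets follow largely from that selection. Whether the sets responded differently could hardly be tested, since set A holds 1 vector library and set B 1 ERG library. The interaction term in edgeR gave 0 calls among 14203 genes and 1446 genes (10.2%, against 5% by chance) at an unadjusted p under 0.05.

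**Figure D1:**
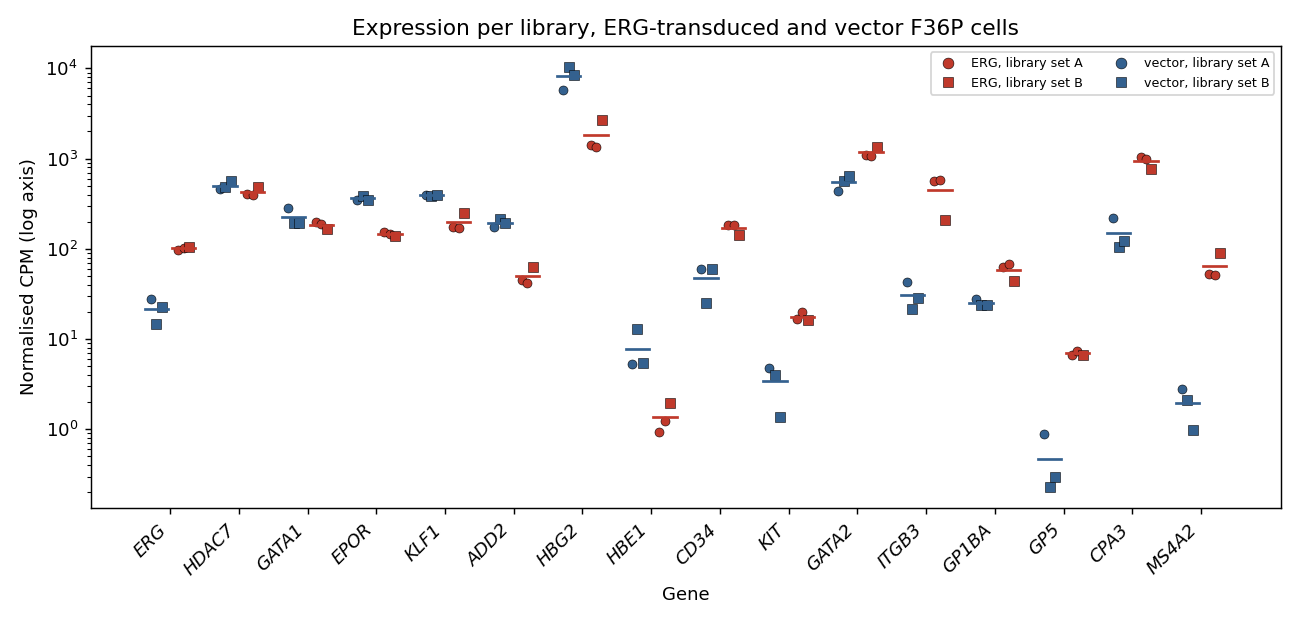
Normalised CPM on a log axis of 16 genes in each of the 6 libraries, with bars at group means (n = 3), ERG in red, vector in blue, and circles and squares for the libraries of set A and set B. ERG, CD34, KIT, GATA2, ITGB3, GP1BA, GP5, CPA3 and MS4A2 lie higher in all 3 ERG libraries, EPOR, KLF1, ADD2, HBG2 and HBE1 lie lower, and HDAC7 and GATA1 did not pass the test.

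All 10 tested haemoglobin genes had negative log2 fold changes (median -1.91), and 3 of them passed over all genes, 8 when adjusted over the list alone and 8 with the set term. HBG2 (1819 ± 747 against 8185 ± 2286 CPM; log2 -2.17, SE 0.36, edgeR adjusted p = 0.032) and HBG1 (202 ± 110 against 806 ± 123 CPM) encode the fetal gamma chains, and HBE1 (1.38 ± 0.53 against 7.82 ± 4.31 CPM) the embryonic epsilon chain. The alpha globin genes HBA1 and HBA2, chosen after their values were seen, had log2 differences of -1.74 and -1.82 (edgeR adjusted p = 0.0683 and 0.0859; with the set term 5.4e-05 and 1.0e-04). Both also passed without ERG replicate 3 (0.025 and 0.0385) or vector replicate 1 (0.0389 and 0.0379). HBG1 and HBG2, like HBA1 and HBA2, are near-identical copies, so the split of reads within each pair is uncertain. The camera test gave adjusted p = 4.5e-13 for the list, and adjusted p = 0.127 with an estimated correlation.

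Of 19 haem synthesis and iron genes, 18 had negative fold changes (median -0.56), of which 2 passed over all genes, 9 when adjusted over the list alone and 12 with the set term. The mitochondrial transporter ABCB10 fell 1.89-fold. ALAS2, the erythroid enzyme of the first step of haem synthesis and chosen after its value was seen, was at 47.7 ± 9.26 against 123 ± 43.4 CPM with an edgeR adjusted p of 0.0517 (2.57-fold). It passed with the set term (log2 -1.56, adjusted p = 4.4e-05) and without vector replicate 1 (-1.04, 0.0425). The list had a camera adjusted p of 4.7e-08 (adjusted p = 0.127 with an estimated correlation). Among 25 red cell membrane and blood group genes (median -0.59), 3 fell over all genes and 0 rose. Adjusted over the list alone 11 were lower and 2 higher, and with the set term 15 and 2. ADD2, an adducin of the membrane skeleton, fell 3.91-fold (50.0 ± 11.1 against 195 ± 19.2 CPM), and ACKR1, the Duffy blood group receptor, 2.05-fold. SLC4A1, the anion exchanger of the red cell, was at 11.3 ± 5.67 against 64.8 ± 33.8 CPM without passing (edgeR adjusted p = 0.0732), and was named after its value was seen. It passed with the set term (log2 -2.95, adjusted p = 0.00168). The camera adjusted p was 1.1e-07 (adjusted p = 0.127 with an estimated correlation).

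Of 19 erythroid regulators (median -0.26), 3 fell and 0 rose, with 4 lower when adjusted over the list alone and 7 with the set term. EPOR, on chromosome 19 from 11377205 to 11384342, was at 147 ± 6.72 against 362 ± 22.6 CPM (log2 -1.30, SE 0.13, edgeR adjusted p = 0.01). KLF1, a transcription factor that activates globin and other red cell genes (chromosome 19, 12884422 to 12887199), fell 1.97-fold. LMO2, a bridging partner of GATA and TAL1 proteins, fell 1.92-fold. GATA1 and TAL1, chosen after their values were seen, had log2 differences of -0.28 and 0.01 (edgeR adjusted p = 0.518 and 0.985). Among the alternatives run GATA1 passed only with the set term (log2 -0.39, adjusted p = 0.0246), and TAL1 in none. The list's camera adjusted p was 3.9e-04 (adjusted p = 0.127 with an estimated correlation).

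All 18 tested members of the megakaryocyte and platelet list had positive log2 fold changes (median 2.01). Over all genes 11 rose and 0 fell, with 16 higher when adjusted over the list alone and 15 with the set term. ITGB3, which pairs with ITGA2B as the fibrinogen receptor of platelets (chromosome 17, 47253846 to 47311816), was at 570, 578 and 211 CPM in the ERG libraries and 43.2, 21.6 and 28.6 CPM in the vector libraries (log2 3.86, SE 0.46, edgeR adjusted p = 0.0128). LTBP1, a binding protein of latent TGF-beta, rose from 13 counts in the 3 vector libraries to 1086 in the ERG libraries. Its differences of log2 CPM, with a prior count of 2, were 6.72 within set A and 3.84 within set B. Members of the platelet surface or granules rose from very few counts: PPBP had 4 and SELP 5 counts in the 3 vector libraries together, against 307 and 373 in the ERG libraries. CLEC1B had 84 counts against 1, a ratio of 69.3 (95% counting interval 12.1 to 2768). Leaving out the vector library with all of these few counts moved the fitted log2 change from 5.88 to 9.64 for PPBP (vector replicate 3, edgeR adjusted p = 0.112) and from 5.73 to 7.74 for CLEC1B (vector replicate 1, 0.051). With no vector count left, these sizes are not measures of a larger change. For SELP, leaving out the vector library with most of its counts moved it from 5.87 to 7.42 (vector replicate 1, 0.0403). Without vector replicate 2, which held 0 counts of them, PPBP and SELP were at 5.25 and 5.23 (0.183 and 0.131). Chosen after their values were seen, MMRN1 rose 7.49-fold, RAB27B 5.07-fold, PLEK 4.56-fold, the thrombin receptor F2R 3.22-fold and GP1BA 2.34-fold, while ITGA2B was at 1496 ± 396 against 762 ± 301 CPM without passing (edgeR adjusted p = 0.209). With the set term ITGA2B passed as higher (log2 0.73, adjusted p = 0.0107). In the ERG libraries of set A the list stood 1.61 and 1.59 above the mean of the 6 libraries on the log2 scale, and in that of set B 0.36 above it. The vector libraries stood at -0.93, -1.47 and -1.17. The camera adjusted p was 2.8e-30 (adjusted p = 0.127 with an estimated correlation).

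Of 11 tested mast cell, basophil and eosinophil genes (median 1.20), 4 rose and 0 fell. Adjusted over the list alone 8 were higher, and with the set term 7 were higher and 1 lower. MS4A2, the beta chain of the high-affinity IgE receptor (chromosome 11, 60088261 to 60098466), was at 65.0 ± 22.5 against 1.98 ± 0.929 CPM (log2 5.02, SE 0.41, edgeR adjusted p = 0.01). CPA3, the mast cell carboxypeptidase (chromosome 3, 148865256 to 148897196), was at 932 ± 141 against 150 ± 61.7 CPM (log2 2.64, SE 0.31). MS4A3 rose 5.20-fold (8.22-fold without vector replicate 1) and the prostaglandin D synthase HPGDS 3.16-fold. HDC, the histidine decarboxylase, and PRG2, the eosinophil major basic protein, were named after their values were seen. They were already at 556 ± 99.5 and 941 ± 360 CPM in vector libraries and did not pass (773 ± 91.5 and 654 ± 56.4 CPM with ERG; edgeR adjusted p = 0.271 and 0.391). PRG2 was the member that passed as lower with the set term (log2 -0.65, adjusted p = 0.0188). The camera adjusted p was 5.7e-12 (adjusted p = 0.127 with an estimated correlation).

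**Figure D2:**
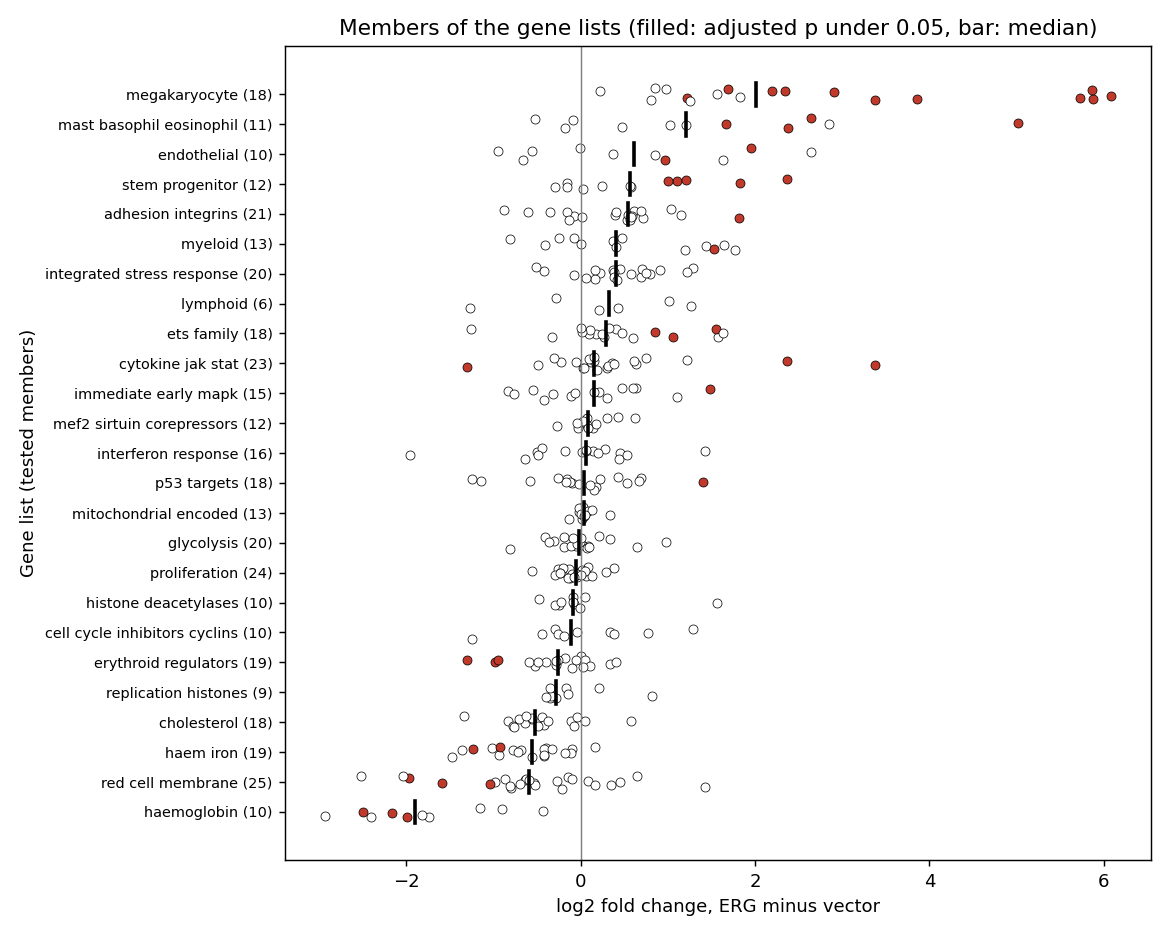
The log2 fold change (ERG minus vector) of every tested member of 25 gene lists, with the number of members in brackets. Filled points passed an edgeR adjusted p of 0.05 over all genes, open points did not, and bars are list medians, from 2.01 for the megakaryocyte list to -1.91 for the haemoglobin list.

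Among 12 tested stem and progenitor genes (median 0.57), 5 rose and 0 fell, with 6 higher when adjusted over the list alone and 6 with the set term. KIT, the receptor of stem cell factor, rose 5.16-fold, CD34 3.54-fold (170 ± 23.1 against 48.0 ± 19.8 CPM; chromosome 1, 207880972 to 207911402), ANGPT1 2.30-fold and GATA2 2.15-fold. GATA2, a GATA factor of progenitors, was at 1177 ± 148 against 548 ± 107 CPM (log2 1.10, SE 0.20, edgeR adjusted p = 0.0416; chromosome 3, 128479427 to 128493185). MSI2 was the fifth gene and was named after its value was seen (2.00-fold). The camera adjusted p was 2.2e-06 (adjusted p = 0.127 with an estimated correlation). Of 18 ETS family genes other than ERG (median 0.29), 3 rose and 0 fell, with 6 higher and 1 lower when adjusted over the list alone and 4 higher with the set term. ELK3 rose 2.92-fold, FLI1, the closest relative of ERG, 2.08-fold and ETV6 1.81-fold. SPI1, the factor PU.1, named after its value was seen, had a log2 difference of 0.17 (edgeR adjusted p = 0.736). The camera adjusted p was 4.3e-04 (adjusted p = 0.212 with an estimated correlation).

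Endothelial genes, several of which blood progenitors also express, gave 2 rises and 0 falls among 10 tested (median 0.61), with 5 higher and 3 lower when adjusted over the list alone and 6 and 2 with the set term. PECAM1 rose 3.87-fold and the angiopoietin receptor TEK 1.95-fold (camera adjusted p = 0.0117, adjusted p = 0.411 with an estimated correlation). The list did not pass without vector replicate 3 (camera adjusted p = 0.074) or in 6 limma settings with all libraries (0.116 to 0.159), though it did with quantile normalisation (0.0394). Of 21 adhesion and integrin genes (median 0.54), 1 rose, CD44, the hyaluronan receptor, by 3.53-fold. Adjusted over the list alone 7 were higher and 1 lower, and with the set term 8 and 2. The camera adjusted p was 0.00305 (adjusted p = 0.411 with an estimated correlation), and 0.0505 without vector replicate 3. Of 13 granulocyte and monocyte genes (median 0.41), 1 rose, the Fc receptor chain FCER1G, by 2.88-fold, with 2 higher when adjusted over the list alone. That list moved both ways with the set term, 3 higher and 4 lower. Its camera adjusted p was 0.0396 (adjusted p = 0.912 with an estimated correlation), and it did not pass in 14 of 22 alternatives (adjusted p 0.0504 to 0.379), 10 of them with all libraries, among these the set term (0.211) and limma on log2(CPM + 1) (0.117).

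Among 23 cytokine receptor and JAK-STAT genes (median 0.15; 4 higher and 1 lower when adjusted over the list alone), 2 rose and 1 fell, and with the set term 4 were higher and 3 lower. KIT rose 5.16-fold, from 3.39 ± 1.80 to 17.7 ± 2.17 CPM, while EPOR fell 2.47-fold. The list as a whole did not pass (camera adjusted p = 0.0796, adjusted p = 0.912 with an estimated correlation). At the preset correlation it did in 7 of 22 alternatives (adjusted p 0.00162 to 0.0498), 5 of them with all libraries, such as limma on log2(CPM + 1) (0.0498). The others were without ERG replicate 3 or vector replicate 1. Of 15 immediate early and MAPK genes, FOSL2 alone rose over all genes (2.81-fold), and 3 were higher when adjusted over the list alone. The camera adjusted p was 0.0843 (adjusted p = 0.282 with an estimated correlation). With the set term 3 of the 15 were higher and 0 lower, and the list passed at the preset correlation (camera adjusted p = 0.0234). It passed in 4 of 22 alternatives in all, also with a filter of 5 CPM (0.0153), with ERG replicates 1 and 2 summed and the set term (0.0383) and without vector replicate 2 (0.0252). Of 18 p53 targets PLK3 alone rose (2.65-fold, 1 when adjusted over the list alone; camera adjusted p = 0.846), and with the set term 2 were higher and 2 lower. Of 4 tested stromal and epithelial genes, too few for the list test, the cadherin CDH1 fell 5.06-fold, with 2 lower when adjusted over the list alone and 1 with the set term.

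The other lists had 0 members past the threshold over all genes. Adjusted over the list alone, 1 of 6 lymphoid genes was lower (camera adjusted p = 0.737), 1 of 12 MEF2, sirtuin and corepressor genes higher (0.328) and, of 16 interferon genes, 1 higher and 1 lower (0.847). That count was 0 for 24 proliferation genes (camera adjusted p = 0.649), 10 cyclins and cell cycle inhibitors (0.937), 20 glycolysis genes (0.847), 13 mitochondrially encoded genes (0.847) and 9 replication histones (0.837). It was also 0 for 20 integrated stress response genes (camera adjusted p = 0.328) and 18 cholesterol synthesis genes (0.0584). With the set term, 2 interferon genes were higher and 3 lower, 1 was higher and 2 lower in each of the lymphoid, stress response and cholesterol lists, and 2 were higher and 1 lower in each of the cyclin and glycolysis lists. That term also gave 2 higher proliferation genes and 1 higher gene of the MEF2 list, and 0 calls among mitochondrially encoded genes and replication histones. Some of these lists passed in other settings. The cholesterol list did so in 11 of 22 alternatives (camera adjusted p 1.1e-05 to 0.0484), 9 of them with all libraries, such as limma on log2(CPM + 1) (0.0285), and the others without ERG replicate 3 or vector replicate 1. With the set term the median of the cholesterol list went from -0.52 to -0.05 and it did not pass (camera adjusted p = 0.542), nor did it with an estimated correlation (0.923). For the MEF2 list the camera adjusted p was 0.0394 in limma with quantile normalisation. The stress response list passed without ERG replicate 3 (0.0334) and without vector replicate 1 (5.5e-04), the proliferation list without vector replicate 1 (0.0192) and the mitochondrially encoded genes without vector replicate 2 (0.0089). The 2 members of each list with the highest mean CPM did not pass. Their log2 differences were -0.28 for CD7 and 1.02 for CD79A, 0.09 for CHD4 and -0.04 for HSPA9, -0.64 for BST2 and 0.44 for IFITM3, -0.05 for MCM7 and -0.10 for MCM4, and -0.44 for MYC and 0.34 for CCND3. They were 0.07 for GAPDH and 0.01 for ENO1, 0.08 for COX1 and 0.01 for ND4, -0.34 for H2BC12 and -0.17 for H1-2, 0.22 for ATF4 and -0.43 for HSPA5, and 0.05 for SREBF2 and -0.55 for SQLE. With the set term CD7 (-0.44, edgeR adjusted p = 0.0452), MYC (-0.47, 0.0175) and BST2 (-0.53, 0.0168) passed as lower and CD79A (0.73, 0.00548) as higher. Without a library BST2 (ERG replicate 3, 0.0275), CD79A and IFITM3 (vector replicate 1, 0.0479 and 0.0443) passed. The median, mean and camera direction differed in sign for the histone deacetylases (median -0.09, mean 0.01, camera down), the cyclins and inhibitors (-0.12, 0.03, up) and the interferon genes (0.06, -0.04, up).

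The levels of 10 of 25 lists parted the 3 libraries of set A from the 3 of set B, and those of 11 parted ERG from vector. For a given list, parting ERG from vector would be 10% by chance with 6 independent libraries. It may be more here, since ERG replicates 1 and 2 lay so close together. The sets were chosen on these data, so no chance value holds for them. The lists that parted the sets were the stress response, cholesterol, p53, proliferation, glycolysis, interferon, lymphoid, granulocyte and monocyte, cytokine receptor, and adhesion lists. The integrated stress response list stood at 0.94, 0.95 and 1.09 on the log2 scale relative to the 6-library mean in ERG replicate 1, ERG replicate 2 and vector replicate 1. It stood at -1.07, -0.85 and -1.06 in ERG replicate 3 and vector replicates 2 and 3. The cholesterol list stood at -0.80, -0.76 and -0.58 in the libraries of set A and at 0.74, 0.54 and 0.86 in those of set B.

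**Figure D3:**
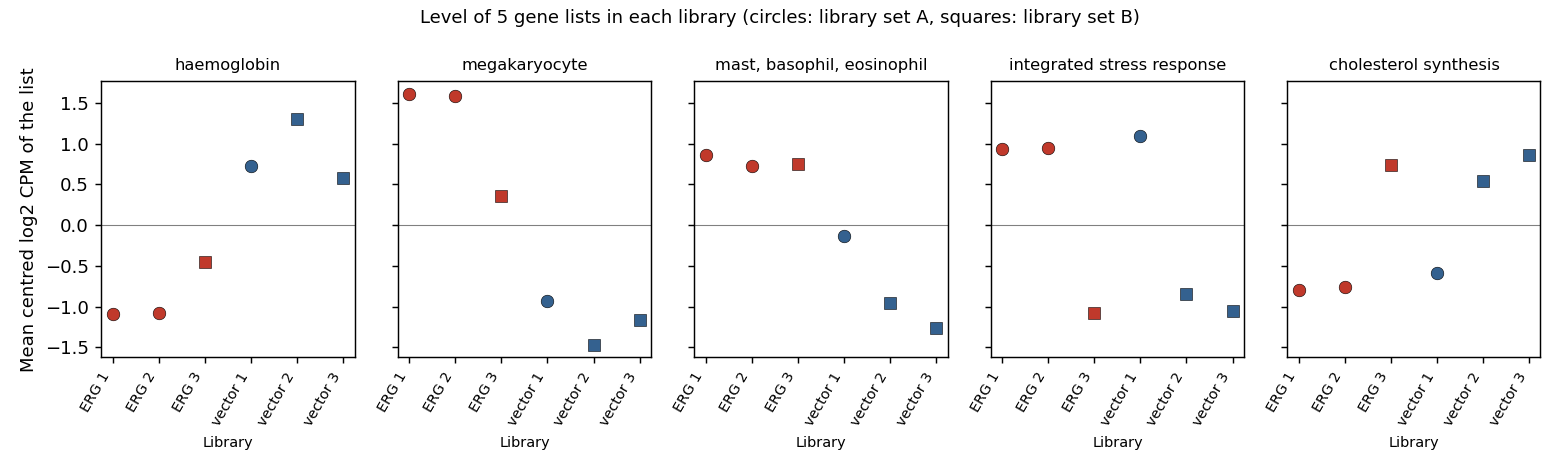
Mean log2 CPM of the members of 5 gene lists in each library, each member centred on its mean over the 6 libraries, with ERG in red, vector in blue, circles for library set A and squares for library set B. Haemoglobin, megakaryocyte and mast cell genes part the groups (haemoglobin -1.08, -1.08 and -0.45 with ERG against 0.73, 1.30 and 0.58 with vector), while stress response and cholesterol genes part the library sets.

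Among all tested genes, in the lists or not, the 12 largest rises under the fixed rule were KIF19, CYP26B1, LTBP1, PPBP, SELP, MS4A2, CYP4F22, DLGAP3, VSTM1, GP5, ITGB3 and ADRA2A. CYP26B1, which degrades retinoic acid, rose from 0.27 ± 0.183 to 24.8 ± 15.6 CPM (log2 6.52, SE 0.68, edgeR adjusted p = 0.011). Without ERG replicate 3 its fitted log2 change was 5.88. Its differences of log2 CPM were 4.74 within set A and 7.05 within set B, with a prior count of 2 that shrinks changes at few counts. The kinesin gene KIF19 had 338 counts in the ERG and 2 in the vector libraries, a ratio of 139 (95% counting interval 38.3 to 1155). Both vector counts were in vector replicate 2, without which its fitted log2 change went from 6.93 to 9.70 and did not pass (edgeR adjusted p = 0.168). With no vector count left, 9.70 is not a measure of a larger change. GP5, a gene of the platelet receptor for von Willebrand factor that is in none of the lists, rose 14.7-fold (log2 3.88, and 4.70 without vector replicate 1). ADRA2A, the alpha-2A adrenergic receptor of platelets among other cells, rose 14.5-fold. CYP4F22 rose 25.2-fold (16.2-fold without vector replicate 2 and 43.2-fold without vector replicate 3), DLGAP3 17.5-fold and VSTM1 17.2-fold (29.4-fold without vector replicate 1). The 12 largest falls were UCA1, HBE1, FOXO6, ARHGAP23, PLPPR3, RNASE1, CDH1, KLK5, HBG2, NYAP1, LGALS3BP and IGFBP5, between 7.15-fold for the long non-coding RNA UCA1 and 4.06-fold for IGFBP5. Without vector replicate 2 the fall of UCA1 was 4.48-fold. RNASE1, a secreted ribonuclease, fell from 144 ± 54.7 to 26.4 ± 2.77 CPM, the kallikrein KLK5 from 187 ± 63.4 to 37.8 ± 5.01 CPM and LGALS3BP from 75.7 ± 16.9 to 18.3 ± 2.75 CPM.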

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

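The library-set term, the summed replicates, scaling by library size, robust edgeR and DESeq2 were chosen after seeing the data. The counts, 313 genes with 209 higher, 104 lower and 246 changed at least 2-fold, stayed within 1.5 times under every limma setting, both filters, median-ratio size factors, library size only and robust edgeR. In these settings between 252 (limma without intensity trend) and 312 (edgeR with no filter) of the 313 genes passed again. None of the 313 changed sign in any setting, though they were selected on the same libraries. Leaving out each library gave 0 to 441 calls, 0 to 309 higher, 0 to 139 lower and 0 to 351 at least 2-fold. edgeR called 0 without ERG replicate 1 or 2, 19 without vector replicate 2, 51 without vector replicate 3 and 441 without ERG replicate 3 or vector replicate 1. DESeq2 called 410, 411, 561, 676, 1707 and 1493 in the same order. With ERG replicates 1 and 2 summed, edgeR called 0 genes, 0 higher, 0 lower and 0 at least 2-fold (1277 at an unadjusted p under 0.05), limma 0 and DESeq2 422, of which 304 are among the 313. Fewer libraries were tested in these fits. The library-set term gave 1869 calls (1022 higher, 847 lower, 612 at least 2-fold), and 1001 with the 2 replicates summed (574, 427 and 493). DESeq2 gave 1006 (596, 410 and 556). All 313 genes were among the calls of these last 3 fits.

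The replicate numbers pair the libraries only in part. Deviations from the group means of same-numbered libraries correlated at 0.628, -0.285 and 0.589 across genes, and vector replicate 2 correlated best with ERG replicate 3. With the replicate number as a block, 905 genes passed (582 higher, 323 lower, 571 at least 2-fold), all 313 included. Replicate 1 of both groups is in library set A and replicate 3 of both in set B. The block therefore takes up part of the difference between the sets. Whether this accounts for the added calls was not tested.

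The log2 fold change of ERG lay between 2.01 and 2.46 when each library was left out. It no longer passed without ERG replicate 1 (2.25, adjusted p = 0.0716), ERG replicate 2 (2.22, 0.0729) or vector replicate 3 (2.25, 0.0544), or with ERG replicates 1 and 2 summed (2.23, 0.0738). Its adjusted p over all 23 alternatives ranged from 4.9e-15 to 0.0738. HDAC7 stayed negative and not past the threshold in all 23 (adjusted p 0.258 to 0.932). In place of 11 gene lists, between 8 and 15 passed when a library was left out and 0 with an estimated correlation. None of the 11 changed the sign of its median, and 8 passed in every fit with the preset correlation. Of 81 genes named here that passed, 64 did so in every setting apart from those with a library left out or ERG replicates 1 and 2 summed without the set term. None of the 81 changed sign. Of 36 named genes that did not pass, 16 did so in some alternative, 15 with the library-set term, 8 with the replicate number as a block, 8 in DESeq2 and 8 with a library left out. Among results that did not pass, 14 named genes and 7 lists changed sign in some setting, without passing there in the other direction. Depth limits the precision of genes with few counts, such as PPBP, SELP, CLEC1B and KIF19, with 4, 5, 1 and 2 counts in the 3 vector libraries together.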

Other observations

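Outside the fixed lists, 272 of the 313 genes passed, and those named in this and the next paragraph were chosen after their values were seen and not tested for enrichment. Further genes of red cell function fell with ERG. The transferrin receptor TFR2 fell 3.46-fold (98.6 ± 8.78 against 341 ± 61.6 CPM, SD, n = 3 each), the pyruvate kinase PKLR of red cells and liver 3.04-fold, the biliverdin reductase BLVRB 2.86-fold, carbonic anhydrase CA1 1.94-fold and catalase CAT 1.64-fold. The neighbouring apolipoprotein genes APOE and APOC1 fell 2.86-fold and 2.46-fold, APOE from 3940 ± 1024 to 1379 ± 39.4 CPM. Genes of phosphoinositide 3-kinases went both ways: the catalytic PIK3CG and the regulatory PIK3R6, which work as a complex, rose 2.60-fold and 4.89-fold and PIK3C2B rose 2.44-fold, while the catalytic PIK3CD and the regulatory PIK3R2 fell 2.14-fold and 2.29-fold. Semaphorin receptors PLXNA1, PLXNA2 and PLXNC1 fell 3.14-fold, 2.74-fold and 1.99-fold and the ligand SEMA4C 2.44-fold, while NRP2 rose from 7 to 169 counts. The edgeR adjusted p of these genes lay at or below that of CA1, 0.0422.

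Among other rises, IL1RL1, the IL-33 receptor of mast cells, rose 8.64-fold (31.3 ± 1.60 against 3.64 ± 1.16 CPM), the kinase SRC 9.93-fold, the scavenger receptor STAB1 5.60-fold, the Notch ligand JAG1 2.52-fold, and the transcription factors GFI1 and SOX4 2.44-fold and 2.07-fold. The histone deacetylase HDAC5 was at 47.1 ± 18.5 against 15.9 ± 12.7 CPM, past the threshold with the library-set term (adjusted p = 0.00121), with the replicate number as a block (0.0203) and without vector replicate 1 (0.0344), but not in edgeR with neither term on all 6 libraries (0.232). The first 13 rows of the deposited table are genes of several chromosomes that stand before a run of mitochondrially encoded genes. They are SYTL4, PECAM1, ITGB3, GP1BA, FLI1, PIK3CG, F2R, KIT, GATA2, PIK3C2B, ATP1B1, FCER1G and CLU, and all 13 were higher with ERG and past the threshold in edgeR, also with the set term. Some of them are also in the fixed lists. The sources used here do not say why these genes stand first. If they were picked for their change in these same libraries, that all 13 passed follows from the choice and is no separate result.

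All tests in the paragraphs that follow were written down after the results were seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 313 genes, and 2 of 10 splits gave as many, since the split of library set A against library set B gave 3400 and every other split gave fewer. The same 2 of 10 splits gave as many on the larger side (209 in the real split, highest other 1862), on the smaller side (104, highest other 1538) and at least 2-fold (246, highest other 939). The sets were defined from the correlations of these same libraries, so the large count of the set split restates that structure and is no separate evidence for it. For the lists, 6 of 10 splits gave at least 11 calls (highest other 13). With the set term, 9 splits keep the makeup of the sets, again too few for a share under 0.05. The real one gave 1869 genes, as many as 1 of 9 splits, and the highest of the others was 0 in edgeR, with up to 764 at an unadjusted p under 0.05.

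The first pattern is that the libraries fall into 2 sets that cut across ERG and vector. Had the labels of ERG replicate 3 and vector replicate 1 been swapped, vector replicate 1 would hold more ERG, but ERG was 3.70 times as high in ERG replicate 3 as in vector replicate 1, beyond the 1.92 between vector libraries. Sequencing depth would part the totals of the sets, but the library of set A had the higher total in 4 of the 9 pairs of a library of each set, which argues against depth. Stress response and cholesterol genes follow the sets in the values per library. So does the share of mitochondrial ribosomal RNA, at 1.35%, 1.41% and 1.53% of counts in set A and 0.41%, 0.89% and 0.46% in set B. A difference in culture or harvest may lie behind the sets, but the labels give no such detail and this stays untested.

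The second pattern is that 11 of 73 erythroid list members passed as lower and 15 of 29 megakaryocyte and mast cell members as higher with ERG, in lists that passed at the preset but not at an estimated correlation (adjusted p = 0.127). The groups hold unequal shares of the library sets. Even in the set where it was smaller, the median log2 change of the 73 erythroid list members was -0.52 (SE over members 0.09), against -0.53 without regard to sets. That of the 29 was 1.62 (SE 0.34), against 1.69. Values within a set are differences of log2 CPM with a prior count of 2, which shrinks changes at few counts. Those without regard to sets come from the edgeR fit. These SEs cover spread between genes and not between libraries, as set A holds 1 vector library and set B 1 ERG library. With the set term 42 of the 73 passed as lower and 2 as higher, and 22 of the 29 as higher and 1 as lower. A lower share of erythroid-like cells would raise the markers of other types alike, if those types kept their proportions to each other. Yet the megakaryocyte list's median exceeded that of the granulocyte and monocyte list by 1.61 on the log2 scale (95% bootstrap interval over members 0.25 to 3.37). A change in those proportions was not tested by this comparison. The interval covers spread between genes and not between libraries, and the granulocyte and monocyte list parted the library sets and not the groups. With the set term the medians were 1.71 for the megakaryocyte list and 0.16 for the granulocyte and monocyte list. Mast cells mixed into the ERG libraries would bring tryptase as well, and the 3 tryptase genes together rose 0.0958 times as many CPM as CPA3, but counts of near-identical copies can miss reads, so this stays open for the mast cell part. A change of expression within the cells by ERG, or the outgrowth of a part of the line, may also account for the pattern, and neither was tested.

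The third pattern is that ERG replicates 1 and 2 are far closer to each other than other libraries are. If every read were an independent draw, a library deposited under both names would give a chi-square of about 1 per degree of freedom, at most 1.04 at 3 SD. The value was 2.20. Reads counted more than once would raise that limit, so the test cannot decide whether the same library underlies ERG replicates 1 and 2. Whether they are separate libraries of the same culture cannot be told apart from separate cultures treated alike, since no label names the culture, and the next closest pair, vector replicates 2 and 3, was at 21.6. If ERG replicates 1 and 2 were of the same culture or library, the fit with both summed may be the better guide. It had 0 genes past the threshold in edgeR without the set term and 1001 with it.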
